A study of Homo sapiens with 3 samples.

How the data were processed

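The study measured gene expression on Affymetrix arrays in 3 cultures of HT-29 cells, described by the series as biological replicates. Per the labels' protocols, cells were plated at 50000 cells per cm2 for 24 h in McCoy's medium with 10% serum under 5% CO2, and were then treated with 200 U/ml IFN-γ for 24 h. RNA was purified with a commercial kit and made into biotin-labelled cRNA, per the labels' protocols. Signals were computed with Affymetrix Expression Console 1.1 and MAS5, per the submitters' processing notes. The deposited values are linear intensity per probe set, not on a log scale. The mean of each array, without the highest and lowest 2% of values, was 500.3, so the arrays had been scaled to a common level before deposit. The scaling target, the background step and the presence calls were not given in the sources used here, and no scanner files were analysed here. The median signal was 137, 144 and 141 on the arrays of replicates 1, 2 and 3, and the 100 brightest probe sets held 11.5%, 12.6% and 15.5% of all signal.

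Values were present for 22277 of 22283 probe sets, and 6 were empty on all arrays. In the platform annotation, 19071 probe sets had 1 gene symbol, 1043 had several and 2163 had none listed, which leaves them unnamed here. Only probe sets with 1 symbol were used to name a gene. They named 11963 genes. Older symbols of list genes were matched through a RefSeq table of assembly GRCh38.p14, used for names alone, and no genome sequence was used.

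The names were first compared with the values. A gene with several probe sets should have related signals on them, and under the deposited order it did not: r was 0.19 over 4310 genes, and -0.02 over the 2433 genes whose probe set names differ in their leading characters. All 3001 uniform displacements of the names, up to 1500 rows either way, were then tried. The peak was at 487 rows (r = 0.50), and the highest value away from the displacements used was 0.25. The order finally used places 15 unnamed values first, then the 100 probe sets numbered from 200000, then 493 probe sets with lower numbers, then 21622 others in file order, and 47 unnamed values last. This moves 19315 probe sets by 487 rows and 2307 by 488 rows. It gave r = 0.60 over all these genes, 0.55 over those with different leading characters and 0.78 over 208 genes of the fixed lists (0.25 as deposited). The 2 moved blocks were checked on their own against other probe sets of the same genes. Over 42 probe sets of the first block r was -0.07 as deposited and 0.43 re-ordered, and over 446 of the second it was 0.01 and 0.34. The median log2 signal of housekeeping minus tissue-restricted probe sets was 1.56 as deposited, 8.37 re-ordered and at most 4.73 under another displacement. The order was chosen after seeing the data, and every gene value depends on it. The names of 62 control probe sets could not be assigned, so they were left out, and the planned ratio of 3′ to 5′ control probe sets was not computed.

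Gene lists, tests and alternatives were fixed before the data were examined, apart from the order of the names and the tests said to be added later. Signals were taken to log2 without a pseudocount. A gene was its single-symbol probe set with the highest mean log2 signal. Of 4310 genes with several probe sets, 1500 (34.8%) had some but not all of them above the limit on every array, so a detected gene can have probe sets under the limit. Among the named genes, HLA-E, GBP1, IFNA17, CD58, CASP1, KRT8, CA12, GAPDH, ACTB, COL1A1, MS4A1, PML, CALR, CXCL2, CXCL5, CXCL8, APOL2, HLA-DOA and HLA-DQB1 were read from probe sets with the _x_at suffix, which marks cross-hybridisation, to which related genes can contribute. The background limit of an array was the 95th percentile of 75 measured genes restricted to other tissues. Log2 signal minus this limit was fitted per gene with an intercept in limma 3.58.1 (R 4.3.3), with a variance trend on mean signal. The test was one-sided, with Benjamini-Hochberg adjustment over all 11963 genes and detection at an adjusted p under 0.05. The limit was treated as known, so its own error is not part of these p-values. Detection says that a probe set was brighter than probe sets of genes foreign to the tissue. The 3 arrays are the only group, so no groups were compared. Signals of different probe sets were not ranked against each other.

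The 22 lists covered receptor and JAK-STAT signalling, MHC class I, MHC class II, GTPases and effectors, type I interferon-stimulated genes, chemokines and cytokines, interferon ligands, checkpoint and adhesion, cell death, mucosal defence, epithelial junctions, absorptive colonocytes, goblet and enteroendocrine cells, Wnt and stem cell genes, proliferation, amino acid metabolism and stress, housekeeping, and markers of fibroblasts, endothelium, T and NK cells, B and plasma cells and myeloid cells. Each share was placed among 10000 random lists with the same numbers of probe sets per gene, as a description. Genes with 5 or more probe sets were treated alike in this matching. Spread and deviation were placed among 10000 random lists matched on mean signal in 20 rank bins, for lists with at least 5 detected genes. The rule for named genes took the first 3 detected genes and the first 1 gene not detected in the fixed order of each list, the 5 detected list genes with the largest SD, and the 10 detected genes with the largest SD among probe sets without the _x_at or _s_at suffix. Any other gene named was chosen after its values were seen.

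The alternatives were quantile normalization, limits at the 99th and 90th percentile, a limit from immune and endothelial genes, the median over probe sets, leaving out probe sets with the _x_at or _s_at suffix, a filter on low signals, no variance trend, a rule of being above the limit on all 3 arrays, a pseudocount of 32, and each replicate left out. The detection step was tested on simulated data with the 11963 genes: 97% of 100 genes placed 1 log2 unit over the limit were detected, as were 100% of 100 genes at 2 units, and 3 of 11688 genes under the limit passed (0.0257%). In a simulation of the 4310 genes with several probe sets, names displaced by 300 rows were recovered at 300 rows. This tested the search over uniform displacements, not the moves of the smaller blocks. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.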

Results

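HT-29, an established human colon adenocarcinoma cell line of epithelial origin, was profiled after treatment with interferon-γ (IFN-γ), a cytokine that T and NK cells release and that acts on epithelial cells through its own receptor and JAK-STAT signalling. All 3 arrays measured cultures given 200 U/ml IFN-γ for 24 h, which the series describes as biological replicates. No untreated cultures were analysed here, so the values below are levels in treated cells, and none of them measures a response to IFN-γ. The median signal per array was 137, 144 and 141 in replicates 1, 2 and 3, and the number of arrays limits the precision of every value. The gene values rest on an order of the probe set names that was inferred from the data, because probe sets of one gene disagreed under the names as deposited. Across 4310 genes the log2 signals of the first 2 probe sets of a gene correlated with r = 0.19 and rho = 0.19 under the deposited order and with r = 0.60 and rho = 0.60 under the inferred order, across genes, which are not independent replicates.

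**Figure D1:**
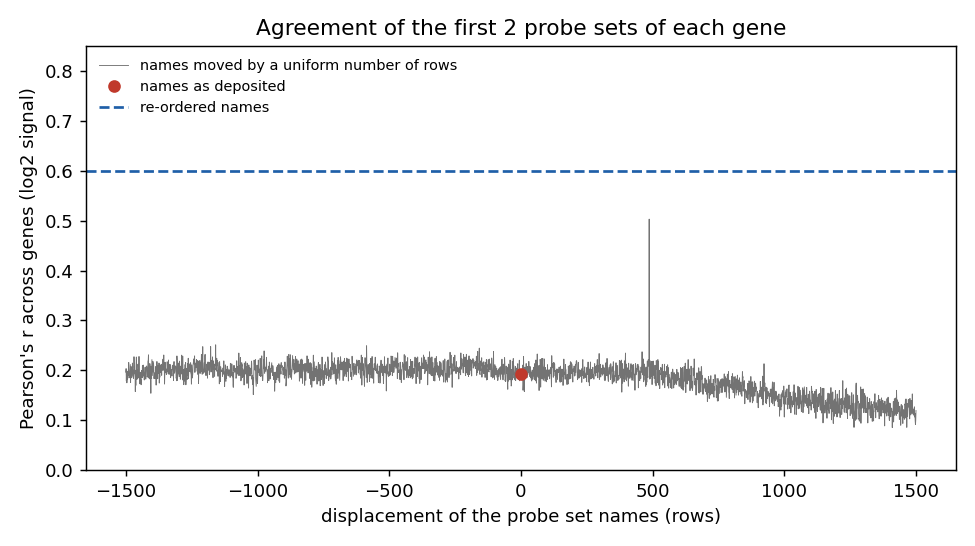
Pearson's r across 4310 genes between the mean log2 signals of the first 2 probe sets of each gene (vertical axis), plotted against the number of rows by which the names were moved (horizontal axis). The red point is the deposited order (r = 0.19), the grey line gives uniform displacements with its peak of 0.50 at 487 rows, and the dashed line is the inferred order (r = 0.60).

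Genes of the IFN-γ pathway, antigen presentation, epithelial junctions and keratins, proliferation and housekeeping were mostly detected in the treated cells, whereas few markers of immune, endothelial and fibroblast cells were. The question asked of each gene was whether its signal lay above the background limit of its array by more than the replicate spread allowed. That limit, the 95th percentile of 75 genes restricted to other tissues, was a signal of 179.9, 169 and 157 in replicates 1, 2 and 3. With limma's one-sided test and Benjamini-Hochberg adjustment over 11963 genes, 5396 genes (45.1%) were detected, among them 2 of the 75 background genes. Leaving out probe sets whose names carry the _x_at suffix of cross-hybridising designs or the _s_at suffix of designs shared by several transcripts (suffixed probe sets for short) reduced the count to 3198 of 8369 genes. Under the names as deposited, 430 genes passed, of which 319 were also detected under the inferred order.

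**Figure D2:**
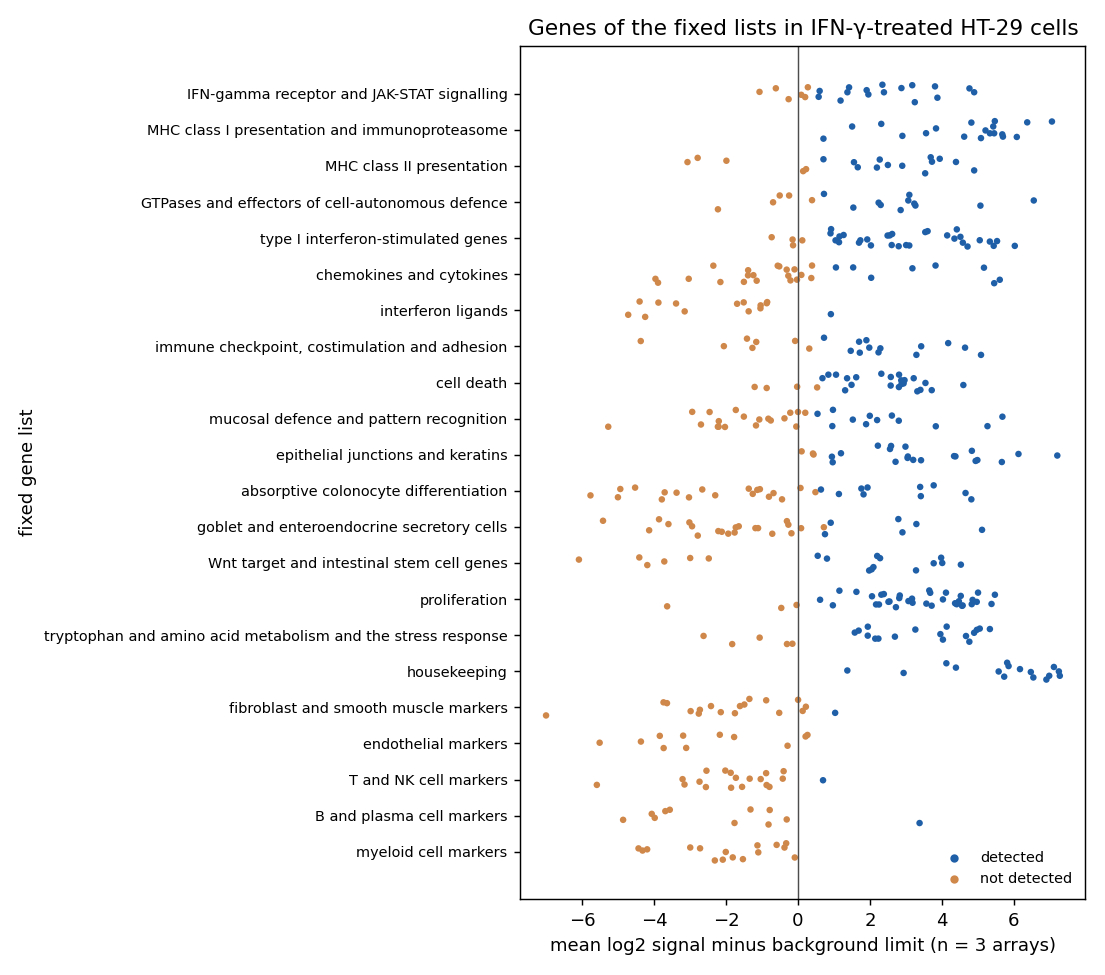
Mean log2 signal minus the background limit (horizontal axis, n = 3 arrays) for each measured gene of the 22 fixed lists (vertical axis), with 1 point per gene, blue where detected and orange where not. All 19 MHC class I genes and all 16 housekeeping genes lie above the limit, and none of the 16 myeloid markers was detected.

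Both chains of the IFN-γ receptor and most of the measured signalling genes were detected. IFNGR1, the ligand-binding receptor chain, had a mean signal of 2544 ± 782 (SD, n = 3), and its partner chain IFNGR2 had 864 ± 130.4 (SD, n = 3). IRF1, a transcription factor known as a primary target of interferon signalling, reached 5085 ± 1076 (SD, n = 3), which was 4.89 log2 units over the limit (limma adjusted p = 4.7e-09). Of the 22 measured genes of the receptor and JAK-STAT list, 16 were detected, and the count was also 16 when adjusted over the list alone. SOCS3, a feedback inhibitor of cytokine signalling, was not detected at 91.4 ± 48.4 (SD, n = 3). The list's share of 72.7% compared with a median of 45.5% among 10000 random lists matched on the number of probe sets per gene, and 1.23% of those lists reached it. Without the suffixed probe sets the count was 10 of 15 genes.

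The MHC class I pathway, which cuts, transports and displays intracellular peptides, was detected throughout. All 19 measured genes passed, and 19 passed when adjusted over the list alone. HLA-E, a non-classical class I molecule, had a mean signal of 7279 ± 958 (SD, n = 3). TAP1, a subunit of the peptide transporter, had 6912 ± 1595 (SD, n = 3), and PSMB9, a catalytic subunit of the immunoproteasome, had 8862 ± 1813 (SD, n = 3). These 3 genes shared the smallest adjusted p of limma's test, 4.5e-09, and none of the random lists reached the list's share. HLA-E was read from a probe set marked as cross-hybridising, so related class I genes can contribute to its signal, and without suffixed probe sets 11 of 12 genes of the list were detected.

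Genes of MHC class II presentation, a pathway of professional antigen-presenting cells that IFN-γ is known to switch on in other cells, were mostly detected. CD74, the invariant chain, had a mean signal of 5348 ± 2155 (SD, n = 3). HLA-DRA, the DR alpha chain, had 3537 ± 201 (SD, n = 3), and HLA-DMA, which helps load peptides, had 2605 ± 396 (SD, n = 3). Of 18 measured genes, 13 were detected, as were 13 when adjusted over the list alone. CIITA, the master regulator of class II transcription, lay at the limit with 186 ± 10.3 (SD, n = 3) and was not detected (limma adjusted p = 0.546, above the limit on 2 of 3 arrays). Among the random lists, 4.27% reached the share of 72.2%, and 7 of 12 genes were detected without the suffixed probe sets.

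GTPases and effectors of cell-autonomous defence, which act against microbes inside the cell, were detected for 11 of 16 measured genes, and for 11 when adjusted over the list alone. GBP1, a guanylate-binding protein, had a mean signal of 5712 ± 976 (SD, n = 3). The tryptophan-degrading enzyme IDO1 had 1443 ± 125 (SD, n = 3), and the tryptophanyl-tRNA synthetase WARS1 had 16036 ± 3461 (SD, n = 3). NOS2, the inducible nitric oxide synthase, was not detected at 108 ± 32.7 (SD, n = 3). Random lists reached the share of 68.8% in 5.18% of draws.

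Interferon-stimulated genes usually described for type I interferon were detected for 30 of 34 measured members, with 30 when adjusted over the list alone. IFIT3 had a mean signal of 1988 ± 426 (SD, n = 3), the ubiquitin-like modifier ISG15 had 7448 ± 1744 (SD, n = 3), and the RNA-sensing enzyme OAS1 had 1002 ± 207 (SD, n = 3). IFI6 was not detected at 189 ± 54.5 (SD, n = 3). The list's share of 88.2% was reached by none of the random lists. The interferon genes themselves were at background apart from 1 of 14, both over all genes and when adjusted over the list alone. IFNG was not detected at 82.1 ± 8.16 (SD, n = 3), and the single exception, IFNA17 at 321 ± 53.99 (SD, n = 3), was read from a cross-hybridising probe set. It had no measurement without the suffixed probe sets, which left 0 of 7 ligands detected.

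The chemokines CXCL9, CXCL10 and CXCL11 were detected, whereas most genes of the chemokine and cytokine list were not. CXCL10 had a mean signal of 7432 ± 1147 (SD, n = 3), CXCL9 had 1541 ± 261 (SD, n = 3) and CXCL11 had 6277 ± 2108 (SD, n = 3). These 3 ligands share the receptor CXCR3, found on T cells. CCL5, another chemokine that attracts T cells, was not detected at 119 ± 26.7 (SD, n = 3), and it was named after its values were seen. IL18, an epithelial cytokine, was not detected at 40.2 ± 15.6 (SD, n = 3). The list gave 8 detected genes of 28 measured, and 8 when adjusted over the list alone. Its share of 28.6% lay under the random median of 46.4%, with 1.54% of random lists below it.

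**Figure D3:**
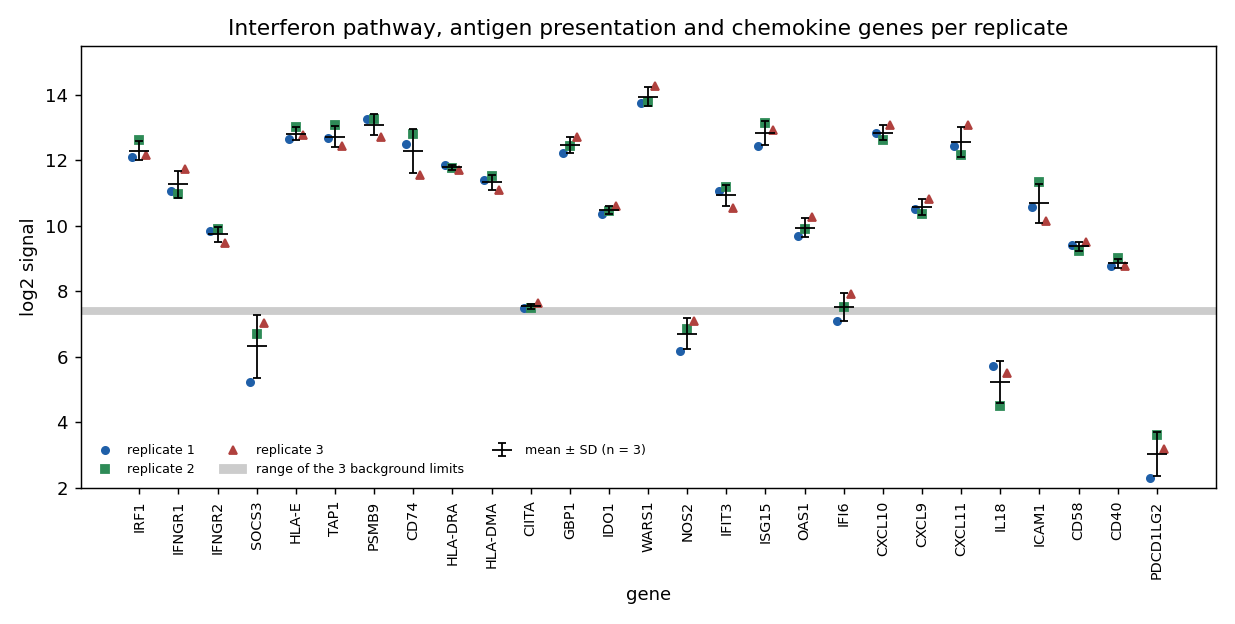
Log2 signal (vertical axis) of the genes named for 7 lists of interferon signalling, antigen presentation, defence, chemokines and adhesion (horizontal axis), with 1 symbol per replicate and the mean ± SD (n = 3) in black. The grey band spans the 3 background limits from 7.30 to 7.49, and CIITA and IFI6 lie beside it.

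Adhesion and costimulation molecules of the epithelial surface were detected in part. ICAM1, a ligand of leukocyte integrins, had a mean signal of 1749.7 ± 753 (SD, n = 3), CD58 had 668 ± 64.9 (SD, n = 3) and the receptor CD40 had 467 ± 46.3 (SD, n = 3). PDCD1LG2, a checkpoint ligand, was not detected at 8.74 ± 3.67 (SD, n = 3). Of 20 measured genes, 13 were detected, and 13 when adjusted over the list alone, a share that 18.2% of random lists reached. CD40 had 1 of 4 probe sets above the limit on all arrays and lay at -1.82 log2 units relative to the limit with their median. CD58 had 3 of 5 and stayed detected with the median (1.42), but lay at -2.67 without the suffixed probe sets.

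Cell death genes were detected for 22 of 26 measured members, and for 23 when adjusted over the list alone, where XIAP was added. CASP1, the inflammasome caspase, had a mean signal of 1687 ± 203 (SD, n = 3). The death receptor FAS had 1246 ± 155 (SD, n = 3), and the initiator caspase CASP8 had 1258 ± 305 (SD, n = 3). CASP5 was not detected at 75.7 ± 25.1 (SD, n = 3). Random lists reached the share of 84.6% in 0.06% of draws.

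Mucosal defence and pattern recognition genes were detected for 12 of 31 measured members, and for 12 when adjusted over the list alone. The iron-sequestering protein LCN2 had a mean signal of 1225 ± 419 (SD, n = 3), and TLR3, a sensor of double-stranded RNA, had 503 ± 166 (SD, n = 3). PIGR, the transporter of secretory antibodies, had 246 ± 7.81 (SD, n = 3) and passed narrowly (limma adjusted p = 0.031). It did not pass when any 1 replicate was left out, with adjusted p between 0.0591 and 0.107. DUOX2, an epithelial oxidase, was not detected at 43.9 ± 28.8 (SD, n = 3). The share of 38.7% lay near the random median of 41.9%.

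Most genes of epithelial junctions and keratins were detected. CDH1, the adherens junction cadherin, had a mean signal of 5232 ± 1127 (SD, n = 3), EPCAM had 8942 ± 3370.3 (SD, n = 3) and the keratin KRT8 had 11967 ± 2674 (SD, n = 3). Of 23 measured junction and keratin genes, 20 were detected, and 20 when adjusted over the list alone, a share that 0.01% of random lists reached. CLDN1, a tight junction claudin, was not detected at 237 ± 74.7 (SD, n = 3; limma adjusted p = 0.141), but it passed when replicate 1, its lowest, was left out (adjusted p = 0.0393). It also passed where genes, those behind the limit included, were taken as the median over their probe sets (adjusted p = 0.0145).

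Differentiation markers of mature intestinal cells were mostly at background. Of 29 measured genes of absorptive colonocytes, 10 were detected, and 10 when adjusted over the list alone, including the brush border protein VIL1 at 589 ± 174 (SD, n = 3), LGALS4 at 4852 ± 1257 (SD, n = 3) and the carbonic anhydrase CA12 at 1841 ± 607 (SD, n = 3). CDX2, an intestinal transcription factor, was not detected at 12.6 ± 3.57 (SD, n = 3). Goblet and enteroendocrine markers gave 6 of 27, and 6 when adjusted over the list alone. TFF3, a secreted trefoil peptide, had 290.1 ± 72.03 (SD, n = 3), AGR2 had 5864 ± 696 (SD, n = 3) and MUC1 had 326 ± 91.8 (SD, n = 3), while the gel-forming mucin MUC2 was not detected at 105 ± 24.0 (SD, n = 3). Only 0.42% of random lists had a lower share than the secretory list, and 7.45% had a lower share than the absorptive list. Without the suffixed probe sets, 2 of 20 secretory and 11 of 27 absorptive markers were detected.

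Wnt target and stem cell genes were detected for 12 of 18 measured members, and for 12 when adjusted over the list alone. MYC had a mean signal of 3888 ± 295 (SD, n = 3), CCND1 had 665 ± 45.96 (SD, n = 3) and SOX9 had 1726 ± 619 (SD, n = 3). LGR5, the marker of crypt stem cells, was not detected at 22.2 ± 8.20 (SD, n = 3). Proliferation genes were detected for 35 of 38 measured members, and for 35 when adjusted over the list alone, a share that no random list reached. MKI67 had 1531 ± 276 (SD, n = 3), the topoisomerase TOP2A had 2195 ± 562 (SD, n = 3) and the mitotic kinase CDK1 had 3763 ± 555 (SD, n = 3). CDC25A, a phosphatase that activates cyclin-dependent kinases, was not detected, with signals of 314, 330.5 and 42.5 in replicates 1, 2 and 3. Without replicate 3 it lay 0.88 log2 units over the limit and passed (limma adjusted p = 0.00197).

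Amino acid metabolism and stress response genes were detected for 17 of 22 measured members, and for 17 when adjusted over the list alone. The asparagine synthetase ASNS had a mean signal of 4321 ± 683 (SD, n = 3), and the stress-induced transcription factors ATF3 and ATF4 had 654 ± 128 and 5689 ± 1389 (SD, n = 3 each). TDO2, a hepatic tryptophan dioxygenase, was not detected at 45.1 ± 35.9 (SD, n = 3). All 16 housekeeping genes were detected, and all 16 when adjusted over the list alone, with GAPDH at 23750.1 ± 5997 (SD, n = 3), ACTB at 21374.5 ± 2475 (SD, n = 3) and TBP at 437 ± 23.9 (SD, n = 3). Housekeeping and tissue-restricted genes had also been set against each other when the order of the names was checked, so their separation is not independent of it.

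Most markers of other cell types were not detected. No endothelial marker of 11 and no myeloid marker of 16 was detected by limma, and 0 of either list passed at an unadjusted p under 0.05. PECAM1, an endothelial adhesion molecule, had a mean signal of 141 ± 36.3 (SD, n = 3), and the monocyte marker CD14 had 112 ± 12.6 (SD, n = 3). Above the limit on all 3 arrays, a rule without a test, were 0 endothelial, 0 myeloid and 3 fibroblast and smooth muscle genes. Of 18 fibroblast and smooth muscle markers 1 was detected, and 1 when adjusted over the list alone. This was the collagen COL1A1 at 378 ± 175 (SD, n = 3), which lay at -1.54 log2 units relative to the limit with the median over its 4 probe sets, while COL1A2 was not detected at 77.9 ± 45.7 (SD, n = 3). Of 19 T and NK cell markers 1 was detected, and 0 when adjusted over the list alone. The cytokine receptor chain IL2RB had 277 ± 58.1 (SD, n = 3) and did not pass without replicate 3 (limma adjusted p = 0.0718). CD3D was not detected at 77.3 ± 44.1 (SD, n = 3). Of 11 B and plasma cell markers 1 was detected, and 1 when adjusted over the list alone. It was SDC1, which epithelial cells also express, at 1802 ± 512 (SD, n = 3), and the B cell marker MS4A1 was not detected at 79.95 ± 45.6 (SD, n = 3).

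The 3 cultures resembled each other in most genes, and replicate 3 stood furthest from replicate 2. Over detected genes the correlation of log2 signals was r = 0.96 (rho = 0.94) for replicates 1 and 2, r = 0.94 (rho = 0.92) for replicates 1 and 3, and r = 0.90 (rho = 0.86) for replicates 2 and 3, across genes, which are not independent replicates. The median absolute difference per gene was 0.27, 0.32 and 0.44 log2 units for the same pairs. The median SD of log2 signal was 0.29 over detected genes, with quartiles of 0.18 and 0.43, and it was 0.48 over genes not detected. Without replicate 3 the median over detected genes was 0.19, but an SD over 2 arrays is not directly comparable with one over 3.

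Among detected genes of the fixed lists the largest replicate spread was that of PML, a nuclear body scaffold, with signals of 468, 683 and 131 in replicates 1, 2 and 3 and an SD of 1.25 log2 units. PML was not detected without suffixed probe sets (limma adjusted p = 0.612) or with the median over its 8 probe sets (adjusted p = 0.205). BAX, a pro-apoptotic protein, followed with an SD of 1.21, the chaperone CALR with 1.17, the anti-apoptotic BCL2L1 with 1.12 and the transcription factor IRF2 with 0.93. Outside suffixed probe sets, the largest spreads of all detected genes were those of the heat shock factor HSF1 (1.39), PTPRO (1.38), MID1IP1 (1.33), SLC4A2 (1.23) and LRP5 (1.22). IGFBP4 (1.22), PAK4 (1.17), STK11 (1.16), NUCB1 (1.14) and RHBDF2 (1.12) completed these 10 genes. All 15 of these genes had their lowest signal in replicate 3. PML, HSF1, MID1IP1, LRP5, STK11 and RHBDF2 lay under that array's limit of 157 there, with signals from 117 to 142. Their SDs and ranks therefore rest in part on background-level values. LRP5 was no longer detected without replicate 1, without replicate 2 or after quantile normalization (limma adjusted p = 0.134, 0.178 and 0.0745), MID1IP1 without replicate 1 (adjusted p = 0.0551), and STK11 with the median over its 2 probe sets (-0.53 log2 units relative to the limit).

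Of 44 detected genes with an SD over 1 log2 unit, 41 were lowest in replicate 3, 3 in replicate 2 and 0 in replicate 1, against 44.8% of all detected genes that were lowest in replicate 3. The other members included AGRN, with signals of 1857, 4652 and 700.2 in replicates 1, 2 and 3, and SLC25A1, with 1979, 3244 and 624, which were named after their values were seen. Most of the 44 genes were also highest in replicate 2, so that replicate 1 lay between replicates 2 and 3. The exceptions were BCL2L1, GATC, PAK4, PEX14 and PTPRO, highest in replicate 1, and LMAN1 and ATP13A3, highest in replicate 3. Some of the 44 genes lay under the background limit in replicate 3.

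**Figure D4:**
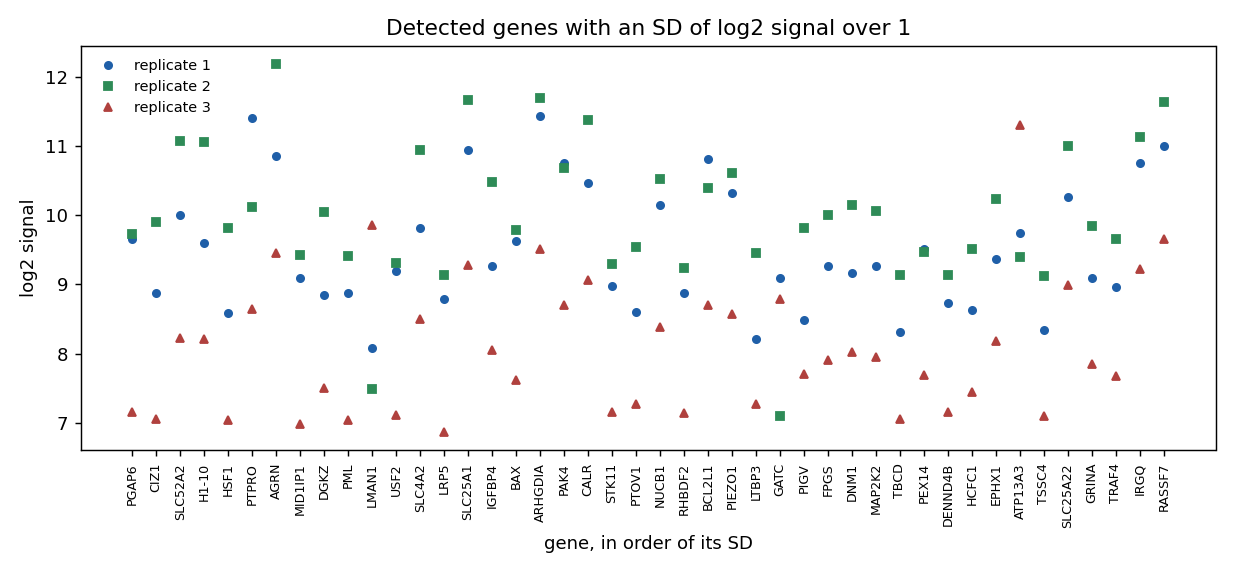
Log2 signal (vertical axis) of the 44 detected genes with an SD over 1 log2 unit (horizontal axis, in order of SD), with 1 symbol per replicate. Replicate 3 is the lowest of the 3 in 41 of the genes.

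Interferon gene groups varied between the cultures about as much as other genes of like signal. The median SD was 0.34 for the receptor and JAK-STAT list, 0.30 for MHC class I, 0.23 for MHC class II, 0.24 for the GTPases and effectors and 0.29 for the type I interferon-stimulated genes, with percentiles of 85.6, 75.3, 15.1, 30.1 and 63.6 among 10000 random lists matched on mean signal. After the median deviation of each array was subtracted, the MHC class I genes lay 0.18 log2 units over their own means in replicate 2, at the 99.8th percentile of random lists. The GTPases and effectors deviated by -0.23 in replicate 1, at the 0.1 percentile. All 11 detected members were above their means in replicate 3 after the same subtraction. Without it this did not hold for all, as SP110 had signals of 1580, 1593 and 1577 in replicates 1, 2 and 3. Proliferation genes deviated by -0.11 and housekeeping genes by -0.28 in replicate 1, at percentiles of 0.83 and 0.07. These deviations were picked as the most extreme over all lists with at least 5 detected genes and all 3 replicates. Some percentiles this far out can come from the number looked at. They are single values per culture, so no test was made of them.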

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

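All tests weighed in this part were chosen after the results were seen. A signal was present outside the named probe sets: of 62 values that carry no probe set name, 22 lay above the background limit on all 3 arrays. Among the 62 values, 19 differed more than 4-fold between arrays. The largest such difference was 66.4-fold, with signals of 774, 11.7 and 138 in replicates 1, 2 and 3. In replicates 2 and 3 that signal lay under the limits of 169 and 157, so the size of this fold rests on background-level values. Other differences over 4-fold can rest on such values too. These values are as many as the 62 control probe sets whose names could not be assigned. The inferred order gives every other probe set with values a row, so under it they would be those of the control probe sets. Which value belongs to which control was not resolved here.

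Probe sets of one gene disagreed under the deposited names. Noise of the arrays is argued against by the lowest correlation between replicate arrays over all values, r = 0.9251, which is far above that of probe sets of one gene. Different transcripts of one gene are argued against as the cause by the gain in r of 0.41 when the same names are put in another order. That order was found by a search for a high r, so part of the gain can come from the search itself. The candidate explanation left is that the names were displaced against the values, with r = 0.60 in the inferred order against at most 0.25 at other displacements. How a displacement arose was not tested, and the inferred order remains a hypothesis found on the same data.

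Detected genes with the largest spread, such as HSF1, SLC4A2 and CALR, were mostly lowest in replicate 3 and highest in replicate 2. The array medians of 137, 144 and 141 in replicates 1, 2 and 3 cannot decide on a different array-wide signal scale. The arrays had been scaled to a common level before deposit, which brings such medians together. The upper quartiles of signal were 547, 544 and 493, so the shape of the distribution still differed in replicate 3. Over the 44 genes the median of replicate 3 minus the mean of replicates 1 and 2 was -1.87 log2 units. It was -1.79 after cyclic loess and -1.78 after quantile normalization, which could change little on arrays already scaled to a common level. Noise of single probe sets is argued against by 31 other probe sets of the same genes, whose median was -1.27, with 83.9% of them below 0, while the median of all named probe sets above the limit was -0.03. Whether the interferon response was weaker in that culture cannot be decided without untreated cultures. By the same difference, the 89 detected genes of 5 interferon and antigen presentation lists were not lower as a group than all detected genes, which were not matched on signal. Their median lay 0.0447 log2 units over that of all detected genes (quartiles of the genes -0.38 and 0.32). In replicate 3 the lists deviated by -0.15 (receptor and JAK-STAT), 0.02 (MHC class I) and -0.03 (MHC class II). Deviations were 0.18 for GTPases and effectors and 0.10 for type I interferon-stimulated genes. In this order their percentiles among random lists matched on signal were 7.91, 6.38, 38.42, 90.55 and 78.07. Against genes of like signal, the receptor and JAK-STAT and MHC class I lists thus lay toward the low end in replicate 3. The GTPases and effectors lay toward the high end, so the lists did not move together and the pooled median hides this. RNA quality, labelling, GC content and a difference between the cultures themselves stay open, since none of them was tested.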

How the results depend on the processing

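The order of the names was added as an alternative after the data were seen, and all other alternatives were planned. Of 299 alternative counts of detected genes, 253 stayed within 1.5 times the reported count, and 46 did not. No paired analysis was possible because the series has 1 group. The 48 alternative list deviations, all of replicate 3, stayed within the list's median SD of the reported value. That bound was wider than each reported deviation, so a change of sign would not have been flagged. The 104 alternative spreads each moved by less than the reported spread, a rule that a decrease could hardly break. Over all genes the 3 correlations were r = 0.96, 0.94 and 0.93, against 0.96, 0.94 and 0.90 over detected genes. The median SD of detected genes ranged from 0.19 without replicate 3 to 0.31 without replicate 1. Both of these SDs are over fewer arrays than the reported one. The count of detected genes ranged from 3768 with the limit at the 99th percentile to 5980 at the 90th among settings that kept the names and all probe sets, and from 5150 to 5416 with each replicate left out.

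Without _x_at and _s_at probe sets, which also leaves fewer genes to test, the counts were 3198 of 8369 over all genes, 10 of 15 measured for receptor and JAK-STAT signalling, 11 of 12 for MHC class I, 7 of 12 for MHC class II, 16 of 22 for type I interferon-stimulated genes, 5 of 20 for chemokines and cytokines and 0 of 7 for interferon ligands. They were 7 of 12 for checkpoint and adhesion, 13 of 19 for cell death, 7 of 23 for mucosal defence, 10 of 12 for epithelial junctions, 2 of 20 for goblet and enteroendocrine cells, 10 of 14 for amino acid metabolism and stress, 7 of 7 for housekeeping and 0 of 10 for fibroblasts.

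With the names as deposited the counts were 430 over all genes, 3 each for receptor and JAK-STAT signalling, epithelial junctions, Wnt and stem cell genes and housekeeping, 2 each for type I interferon-stimulated genes and absorptive colonocytes, and 1 each for MHC class I, MHC class II, cell death, mucosal defence and amino acid metabolism and stress. They were 0 for GTPases and effectors, chemokines and cytokines, interferon ligands, checkpoint and adhesion, goblet and enteroendocrine cells, proliferation, fibroblasts, T and NK cells, and B and plasma cells. Under these names the limit of replicate 1 was a signal of 3614.

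Other settings moved some lists with 0 or 1 detected gene, but not the myeloid list, which stayed at 0 throughout, or the B and plasma cell list, which moved only under the deposited names. Fibroblast markers gave 0 with the limit at the 99th percentile, 2 at the 90th, 0 with the median over probe sets and 3 above the limit on all 3 arrays. Endothelial markers gave 1 with the limit at the 90th percentile and 1 with the median over probe sets. Interferon ligands gave 0 with the limit at the 99th percentile. T and NK cell markers gave 0 with the limit at the 99th percentile, 0 with the limit from immune and endothelial genes, and 0 to 1 with each replicate left out. Their cause was not tested.

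Of 496 alternative values of 87 named genes, 477 kept their side of the limit and of the test, 14 lost detection and 3 gained it. A change of sign came with 4 of these losses and 1 of these gains, and 2 further values changed sign without being detected. Relative to the limit, IFI6 ranged from -0.14 to 0.38 log2 units and CDC25A from -0.54 to 0.88 with each replicate left out, and CDC25A lay at 0.16 without _x_at and _s_at probe sets. CD58 lay at -2.67 without those probe sets. With the median over probe sets CD40 lay at -1.82, COL1A1 at -1.54 and STK11 at -0.53. The cause was not tested. Signals near the limit, such as those of CIITA, IFI6 and CLDN1, are where 3 arrays resolve least.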

Other observations

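The genes in this part were chosen after their values were seen. Within MHC class II, both DP chains were detected, neither DO chain was, and the DQ chains were split. HLA-DPA1 had a mean signal of 1969 ± 315 (SD, n = 3), HLA-DPB1 had 499 ± 68.2 (SD, n = 3) and HLA-DQB1 had 276 ± 24.3 (SD, n = 3), and all were detected. HLA-DQB1 was read from a cross-hybridising probe set, to which related class II genes can contribute, and 2 of its 7 probe sets lay above the limit on all arrays. HLA-DQA1 at 39.8 ± 53.3 and HLA-DOB at 48.4 ± 25.3 (SD, n = 3 each) were not detected. HLA-DOA, at 197 ± 14.6 (SD, n = 3), lay above the limit on all 3 arrays but did not pass limma's test (adjusted p = 0.348). All 4 measured apolipoprotein L genes were detected, with APOL1 at 1418 ± 176, APOL2 at 299.8 ± 126, APOL3 at 807 ± 154 and APOL6 at 835 ± 122 (SD, n = 3 each). APOL2, read from a cross-hybridising probe set, passed narrowly (limma adjusted p = 0.0366) and lay under the limit in replicate 1 with a signal of 157.

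Of the measured neutrophil chemokines CXCL1, CXCL2, CXCL3, CXCL5 and CXCL8, CXCL2 alone was detected, at 353 ± 54.3 (SD, n = 3) on a cross-hybridising probe set. CXCL1 at 219 ± 24.2 and CXCL3 at 228 ± 74.7 (SD, n = 3 each) lay above the limit on all 3 arrays but did not pass limma's test (adjusted p = 0.126 and 0.136). CXCL8 had a mean signal of 117 ± 32.05, CCL2 had 11.9 ± 5.66 and CCL20 had 20.7 ± 3.34 (SD, n = 3 each), and none was detected. The death ligand TNFSF10 was detected at 2390 ± 219 (SD, n = 3), as were the cytokine IL15 at 693 ± 74.7 and the interleukin antagonist IL1RN at 492 ± 75.04 (SD, n = 3 each). VIM, a mesenchymal intermediate filament, was not detected at 61.3 ± 29.4 (SD, n = 3).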
